A study of Solenopsis invicta with 4 samples.

How the data were processed

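CG methylation was measured by whole-genome bisulfite sequencing in 4 whole-body DNA libraries of the red imported fire ant, Solenopsis invicta: workers, alate (winged) queens, haploid males and diploid males. Per the labels, the queen library and each male library pooled DNA of 5 adults, and the worker library pooled 3 extractions of several workers. The series' design text mentions individual males and queens and no pooling of them, so the number of males and queens behind a library rests on the sample labels. Each group was therefore 1 pooled library, and no comparison has a replicate check. Per the labels' protocols, unmethylated lambda phage DNA was added to every sample before bisulfite treatment, and reads were paired ends of 90 nucleotides.

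The deposited table holds counts made by the authors: for each CG site and library, the number of reads calling C (methylated, protected from conversion) and the number calling T (unmethylated). Per the file headers, the 4 column pairs belong to the alate, worker, haploid male and diploid male libraries. FastQC, Bismark, Bowtie2 and SAMtools are named in the submitters' processing notes, without versions or parameters. Trimming, alignment settings, removal of duplicate reads and the origin of the assembly are not given in the sources used here. Coordinates refer to scaffolds named Si_gnF in the table. No gene annotation of that build was used here, so exons, introns and genes are not distinguished and the gene lists fixed in advance were not computed. The coverage of a site reached 8055 calls at most. The table lists 14936211 CG sites, of which 3112 lie on lambda and 14933099 on 10543 scaffolds, and no position is listed more than once. No column was left unused.

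The C share on lambda was taken as the background rate of each library. It was 0.377% in workers (95% Wilson interval 0.368 to 0.386), 0.424% in alate queens (0.413 to 0.435), 0.359% in haploid males (0.351 to 0.368) and 0.359% in diploid males (0.350 to 0.369). All intervals on shares of calls are Wilson intervals, which take calls as independent and cover at most counting error. Reads carried no molecular identifiers, so repeated reads of the same molecule are not allowed for. Intervals on genome-wide values come from 2000 bootstrap draws of whole scaffolds. They cover variation along the genome within these libraries, not variation between ants or pools.

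Genome-wide levels, methylated sites and bins used the 4838096 scaffold sites with at least 5 calls in all 4 libraries, 32.4% of the scaffold sites. A site was called methylated where a one-sided binomial test against the lambda rate gave a Benjamini-Hochberg adjusted p under 0.05. Regions were non-overlapping bins of 1 kb with at least 5 such sites and a mean level over the 4 libraries of at least 5%. The level of a bin is all C calls over all calls of its sites. Bins were compared with a Cochran-Mantel-Haenszel score test stratified by site. Its chi-square was divided by the dispersion between sites, never below 1, and referred to an F distribution with the number of informative sites minus 1 degrees of freedom. Calls at several CGs of the same read entered as separate calls, and the dispersion between sites does not account for that. Where such calls go together, the p-values of bins are too small and the Wilson intervals of bin levels too narrow. Bins with fewer than 2 informative sites were not tested. Bins were ranked by, and median differences are of, the site-stratified difference, which can depart from the difference of the bin's levels where coverage varies from site to site. Single sites were compared with a two-sided Fisher's exact test at the 1928 sites with at least 10 calls in all 4 libraries and a mean level of at least 10%. The distance between libraries was the mean squared difference in level at the same 1928 sites after the binomial sampling variance was subtracted. Benjamini-Hochberg adjustment at 0.05 was applied within each of the 6 pairs of libraries. These tests compare the reads of 2 libraries, not conditions.

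The bins named in the text were chosen by a rule fixed before the data were examined: for haploid against diploid males, alate queens against workers, and diploid males against alate queens, the 5 bins with the largest site-stratified difference in level in each direction among those past the threshold with at least 10 tested sites. Bins and sites from counts of 5 or fewer were named as well, after their values were seen.

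The tests were checked on simulated data with the coverage of the haploid and diploid male libraries and 6036 bins, of which 200 were changed. The bin test recovered 40 of 100 bins changed by 20 points and 70 of 100 bins changed by 40 points, with 0 false calls. Without the dispersion term it recovered 67% and 99%, with 5 false calls. With extra variation between sites it recovered 34% and 67% with 4 false calls, while the same test without the dispersion term gave 165 false calls. In 10 simulations in which all libraries shared the same level at each site, no bin passed in any of the 6 pairs. All simulated counts were drawn separately for each site. They leave out CGs read together on the same molecule, so they do not give the error rate of the bin test in the real data.

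Alternatives covered other coverage minimums, a limit at the 99th percentile of coverage, thinning of every site to its lowest coverage among the libraries, other tests, other minimum levels, differences and bin lengths, rescaling to a median difference of 0, and removal of sites in opposite states. Leaving the alate queen library out of the filters, and thinning for the level and the distance, were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9.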

Results

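DNA methylation at CG sites was profiled in 4 libraries of fire ant whole bodies. Haploid males develop from unfertilized eggs, whereas diploid males, queens and workers carry both parental genomes. The libraries allow a comparison of ploidy within males (haploid against diploid), of caste within females (alate queen against worker) and of sex among diploids (diploid male against alate queen or worker). The worker library held 120261708 calls at scaffold CG sites, the alate queen library 104435123, the haploid male library 131968162 and the diploid male library 121240854. The median coverage of a CG site was 7, 6, 8 and 7 calls in the same order. Calls were present at 97.2% of listed sites in workers, 98.0% in alate queens, 94.7% in haploid males and 98.4% in diploid males.

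Methylation was sparse in every library. The genome-wide CG methylation level was 0.700% in workers (95% scaffold bootstrap interval 0.666 to 0.735), 0.844% in alate queens (0.803 to 0.887), 0.724% in haploid males (0.687 to 0.761) and 0.704% in diploid males (0.668 to 0.740), against 0.359% to 0.424% on unmethylated lambda. The alate queen level exceeded the worker level by 0.144 points (0.133 to 0.155), and the difference on lambda was 0.0470 points. With every site weighted equally, the difference fell to 0.0316 points, and the levels were 0.844% in workers, 0.875% in alate queens, 0.869% in haploid males and 0.810% in diploid males. With equal weights the interval of haploid males minus alate queens included 0 (-0.0117 to 0.000400), and after subtraction of the lambda level alate queens (0.453%) lay below haploid males (0.512%) and workers (0.469%). Haploid males exceeded diploid males by 0.0201 points (0.0138 to 0.0264), and by 0.0599 points (0.0541 to 0.0660) with sites weighted equally, whereas their levels were 0.429% and 0.426% at a coverage minimum of 10 and 0.758% and 0.755% at a minimum of 3. Diploid males and workers differed by 0.00339 points, with an interval that included 0 (-0.00182 to 0.00857), whereas with sites weighted equally diploid males minus workers gave -0.0342 points (-0.0384 to -0.0299). With 1 library per group, none of these differences can be set against variation between pools.

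Few sites were called methylated. The binomial test called 34882 methylated CG sites in workers, 31515 in alate queens, 35791 in haploid males and 34877 in diploid males, 0.651% to 0.740% of the sites tested. Their median level was 50% in workers, 53.8% in alate queens, 57.1% in haploid males and 50% in diploid males, values that depend on the call, since at this coverage a site with a low level seldom passes the test. Of 58198 sites called in any library, 17943 were called in all 4 and 23191 in 1 library alone. The haploid male library had 7579 sites called in it alone, compared with 5500 in workers, 4174 in alate queens and 5938 in diploid males. Under thinning of each site to equal coverage, workers had the most methylated sites, 34092, compared with 32653 in haploid males, and with sites above the 99th percentile of coverage left out the counts were 36366 and 35219.

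Methylation was clustered and lay in CG-poor sequence. Where a methylated site had a tested site 2 to 10 bp farther along the scaffold, the nearest such site was methylated in 63.3% of cases in workers, 65.2% in alate queens, 63.1% in haploid males and 65.8% in diploid males. At 301 to 1000 bp the share was still 34.5% to 35.9%, and at 3001 to 10000 bp it was 12.5% to 14.1%, compared with 0.651% to 0.740% of all tested sites. Among 216754 bins of 1 kb with at least 5 tested sites, 6036 bins (2.78%) had a mean level of at least 5%. These bins held 76.7% of the methylated sites of all such bins. In bins with 20 or fewer listed CGs, 11.1% reached this level, whereas in bins with 81 or more CGs 0.406% did. The level in the same classes fell from 2.20% to 0.418% in workers, from 2.19% to 0.484% in alate queens, from 2.61% to 0.405% in haploid males and from 2.08% to 0.404% in diploid males. At sites with at least 10 calls in every library the CG-poor class was at 0.580% to 0.732%, closer to the CG-rich class at 0.356% to 0.448%, in the same direction. The alate queen library differed from the others in depth across these classes. Over all listed sites its mean coverage, with each site limited to the 99th percentile, decreased from 9.37 calls in the CG-poor class to 4.53 in the CG-rich class, while in haploid males it increased from 3.43 to 10.3. At the tested sites, which need 5 calls in every library, mean coverage without that limit decreased in all 4 libraries, from 24.7 to 7.46 in alate queens, 19.2 to 12.8 in workers, 18.3 to 14.1 in haploid males and 22.1 to 11.1 in diploid males.

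**Figure D1:**
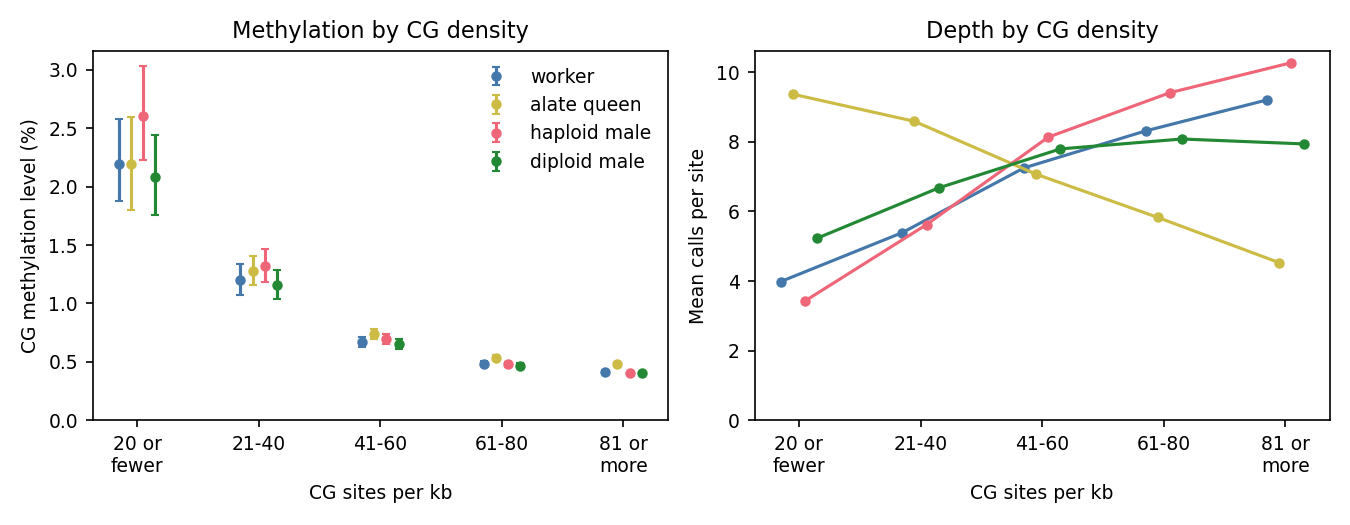
CG methylation level in percent (left, points with 95% scaffold bootstrap intervals) and mean calls per listed site (right, each site limited to the 99th percentile of its library) for 5 classes of CG sites per kb, in worker, alate queen, haploid male and diploid male libraries. The level fell with CG density in all 4 libraries, from 2.08% to 2.61% in the CG-poor class to 0.404% to 0.484% in the CG-rich class, and mean depth over all listed sites fell from 9.37 to 4.53 in the alate queen library.

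Haploid and diploid males differed more than any pair of diploid libraries. After subtraction of sampling variance, the root mean squared difference in site level between haploid and diploid males was 21.3 points (95% scaffold bootstrap interval 19.7 to 22.7). Haploid males stood 21.0 points (19.5 to 22.6) from alate queens and 19.6 points (18.1 to 21.0) from workers. In the pairs without the haploid males the values were 7.37 points (5.78 to 8.76) between alate queens and workers, 10.7 points (9.05 to 12.3) between diploid males and alate queens, and 9.52 points (8.15 to 10.7) between diploid males and workers. The mean squared difference of the 3 pairs with haploid males was 4.93 times that of the other 3 pairs (3.92 to 6.28). This ratio moved with the coverage minimum, to 3.24 (3.07 to 3.40) over 53202 sites at a minimum of 5 and 9.31 (3.85 to 37.5) over 196 sites at a minimum of 20. At the 1928 sites, the mean squared difference of each pair was also fitted by least squares as the sum of a part for each of its libraries. The part was 0.0383 (0.0329 to 0.0439) for haploid males, 0.00720 (0.00507 to 0.00952) for diploid males, 0.00491 (0.00287 to 0.00706) for alate queens and 0.000862 (-0.000835 to 0.00250) for workers. Across the 6036 methylated bins, the level correlated between haploid and diploid males with a Pearson r of 0.868, compared with 0.917 to 0.922 among the 3 diploid libraries. These are correlations across bins, which are not independent replicates.

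**Figure D2:**
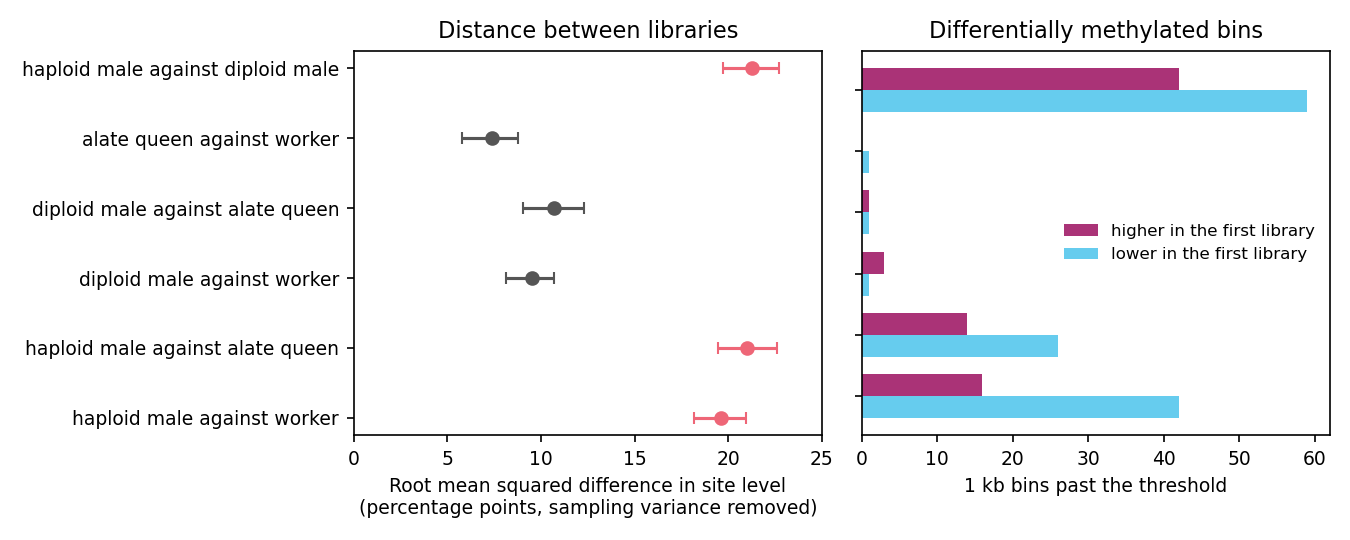
Root mean squared difference in the methylation level of 1928 sites in percentage points, with sampling variance removed (left, points with 95% scaffold bootstrap intervals, pairs with haploid males in red), and number of 1 kb bins past the adjusted threshold in each direction (right), for the 6 pairs of libraries. The 3 pairs with haploid males lie at 19.6 to 21.3 points and the others at 7.37 to 10.7 points.

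At the level of bins, 101 of 5922 tested bins differed between haploid and diploid males at an adjusted p under 0.05, 42 higher and 59 lower in haploid males. Their median difference was 15.7 points, and 4 bins differed by at least 50 points. In the 42 bins with higher values the median level was 22.7% in haploid males and 4.72% in diploid males, while alate queens were at 6.96% and workers at 8.30%. In the 59 bins with lower values it was 9.02% in haploid males and 25.2% in diploid males, with alate queens at 19.7% and workers at 23.6%. Across all 6036 methylated bins the mean level was nevertheless higher in haploid males, 23.6% compared with 22.2% in diploid males, a difference of 1.34 points (1.03 to 1.62). The balance of directions among the bins called depended on the test: without the dispersion term 757 bins were higher and 462 lower, and with Fisher's exact test on summed counts 501 were higher and 395 lower, and in bins of 5 kb 82 were higher and 73 lower. Among single sites, Fisher's exact test called 89 of 1928, of which 57 were higher and 32 lower in haploid males, with a median difference of 61.5 points. At a coverage minimum of 20 the split turned, with 5 sites higher and 24 lower. Thinning to equal coverage left 41 bins, and filters that did not use the alate queen library gave 206 bins.

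The bins with the largest differences between haploid and diploid males showed haploid males apart from all 3 other libraries in most cases. Ranking by that difference itself tends to place the other libraries nearer to diploid males, so this is no separate evidence. On scaffold 02797, the bin from 4471001 to 4472000 had a level of 38.3% in haploid males (Wilson interval 32.6 to 44.2, 264 calls), compared with 2.14% in diploid males, 1.36% in alate queens and 1.32% in workers (adjusted p = 1.94e-05 for haploid against diploid males, site-stratified chi-square on read counts with dispersion correction). On scaffold 03404, the bin from 322001 to 323000 reached 53.7% in haploid males (41.9 to 65.1, 67 calls) and 1.39% in diploid males, with alate queens at 6.80% and workers at 12.3%. On scaffold 05962, positions 1 to 1000 were at 59.4% in haploid males and 15.5% in diploid males, and on scaffold 04785, positions 98001 to 99000 were at 22.7% and 1.19%. The fifth bin with higher values, at 292001 to 293000 on scaffold 09607, was methylated in every library, at 65% in haploid males and 44.6% in diploid males, with a site-stratified difference of 30.2 points. The bins with lower values had intermediate levels in the diploid libraries. Positions 2188001 to 2189000 on scaffold 02551 were at 22.4% in haploid males (18.7 to 26.7, 419 calls), compared with 48.2% in diploid males (43.2 to 53.2, 384 calls), 48.2% in alate queens and 49.2% in workers (adjusted p = 3.33e-06, same chi-square). The next bin of that scaffold, from 2189001 to 2190000, was at 11.8% in haploid males and 44.6% in diploid males. Scaffold 05505 at 209001 to 210000 was at 10.5% and 41.0%, scaffold 07754 at 2001 to 3000 at 12.4% and 45.8%, and scaffold 07050 at 23001 to 24000 at 11.1% and 44.1%.

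**Figure D3:**
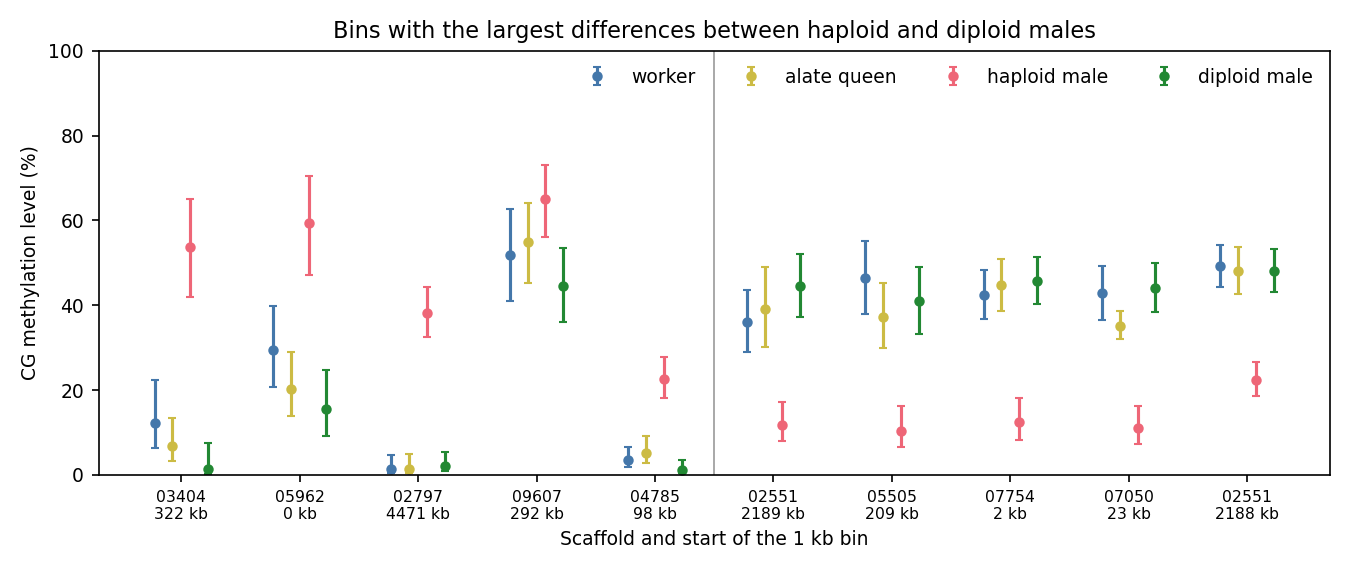
CG methylation level in percent (points with 95% Wilson intervals for counting error) of the 5 bins with the largest increase (left of the line) and the 5 with the largest decrease (right) in haploid relative to diploid males, in all 4 libraries. In the 5 bins on the right, haploid males lie at 10.5% to 22.4% and the 3 diploid libraries at 35.2% to 49.2%. Choosing bins by the difference between the males tends to place the other libraries nearer to diploid males.

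Haploid males also differed from the female libraries. Against alate queens, 40 of 5940 bins were called, 14 higher and 26 lower in haploid males, and against workers 58 of 5926 bins, 16 higher and 42 lower. Both splits depended on the test: without the dispersion term 627 bins were higher and 336 lower against alate queens, and 446 higher and 353 lower against workers. Fisher's exact test on summed counts gave 401 higher and 355 lower against alate queens and 290 higher and 253 lower against workers. Against alate queens bins of 5 kb (51 and 44) and thinning (7 and 5) also turned the split, and filters that did not use the alate queen library raised the count against workers to 160. Single sites gave 64 calls against alate queens, 44 of them higher, and 56 calls against workers, 41 of them higher, but at a coverage minimum of 20 5 of 21 and 7 of 23 were higher. In 21 bins haploid males differed from each of the 3 other libraries in the same direction, 8 higher and 13 lower. The corresponding count was 1 for diploid males and 0 for alate queens and workers. The 3 comparisons share the haploid male library, so part of this overlap can come from that library's own counting error. In 10 simulations without any difference no bin was called in any pair, so their count of 0 does not measure the overlap that a shared library gives. Independent lists of these sizes would share 0.000276 higher and 0.00189 lower bins, a value that leaves the shared library out. With sites above the 99th percentile of coverage left out, 11 bins met this criterion in haploid males, and with thinning 9, of which 5 were higher and 4 lower.

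Alate queens and workers, the female castes, stood 7.37 points apart (5.78 to 8.76), an interval that overlapped that of diploid males and workers (8.15 to 10.7). At a coverage minimum of 20 the mean squared difference was 0.00163 for the castes and 0.00151 for diploid males and alate queens. A single bin of 5928 passed the threshold, at 1989001 to 1990000 on scaffold 01426, with 18.6% in alate queens (13.1 to 25.7, 145 calls) and 51.8% in workers (44.3 to 59.3, 166 calls) (adjusted p = 0.0160, dispersion-corrected chi-square). Haploid males were at 42.1% and diploid males at 46.7% in this bin. No bin was called at a coverage minimum of 10, without a minimum level, or without sites in opposite states, while the test without the dispersion term called 56 bins and Fisher's exact test on summed counts 91. An unadjusted p under 0.05 was found in 344 of the 5928 bins. In simulated data at the depth of the male libraries, 1.33% of unchanged bins had such a p, and 3.55% with extra variation between sites. The simulated test thus gave fewer such bins than the threshold of 0.05 implies. These simulations leave out CGs read together, so they set no expected count. The counts of the other pairs of diploid libraries below are to be read beside the same shares. No single site of 1928 passed Fisher's exact test, with 91 sites at an unadjusted p under 0.05, and the chi-square test also called 0. Over the methylated bins, the mean level was 22.6% in alate queens and 22.8% in workers, a difference of -0.262 points (-0.458 to -0.0664). In simulated data at the depth of the male libraries, 40% of bins changed by 20 points were recovered, and 67% without the dispersion term.

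Between diploid males and alate queens, which differ in sex, 2 of 5927 bins passed, both at an adjusted p of 0.0499. Positions 579001 to 580000 on scaffold 07703 were at 15.6% in diploid males (14.0 to 17.3, 1856 calls) and 8.86% in alate queens (7.85 to 9.98, 2744 calls), with workers at 8.26% and haploid males at 5.99%. Positions 1001 to 2000 on scaffold 06669 were at 8.94% in diploid males and 21.4% in alate queens, with haploid males at 9.05% and workers at 14.6%. No bin was called with sites above the 99th percentile of coverage left out, under thinning or without a minimum level. None was called at a mean level of at least 20%, but both bins lie below that level and were not tested there. An unadjusted p under 0.05 was found in 417 bins. The site at position 197974 of scaffold 10513 was the only single site called, with 0 of 16 calls methylated in diploid males and 90% of 10 calls methylated in alate queens, while workers were at 38.5% and haploid males at 42.9% (adjusted p = 0.00617, Fisher's exact test). No site was called at coverage minimums of 5 and 20, under thinning or without a minimum level. Between diploid males and workers, 4 of 5927 bins passed, 3 higher and 1 lower in diploid males, and 451 had an unadjusted p under 0.05. Each of the 4 had an adjusted p of 0.0434 (dispersion-corrected chi-square). Positions 285001 to 286000 on scaffold 01022 were at 51.9% in diploid males and 33.3% in workers, and positions 788001 to 789000 on scaffold 01722 at 15.4% and 6.85%. Positions 94001 to 95000 on scaffold 04997 were at 17.9% in diploid males and 34.3% in workers, with alate queens at 12.8%. The fourth bin was again the one on scaffold 07703, where diploid males were higher than each other library. Its 21 tested sites held 1069 to 2744 calls per library, compared with medians of 104 to 120 calls per methylated bin. The 99th percentile of coverage was 25 to 30 calls per site, so that setting left out sites of this bin by construction. No bin was called with sites above the 99th percentile of coverage left out, under thinning, without a minimum level or without sites in opposite states. No single site was called by Fisher's exact test, with 104 sites at an unadjusted p under 0.05. The chi-square test also called 0.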

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

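The tests below were chosen after the results were seen, except that on repeated reads of the same molecules, which was set down before its value was known.

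Haploid males stood farther from the 3 other libraries than these stood from each other. After every site was thinned to equal coverage, the mean distance of the pairs with haploid males was 4.87 times that of the other pairs (3.83 to 6.25). The distance at the 1928 sites compared has its sampling variance removed already, so thinning could hardly change the ratio. It is no separate test of unequal numbers of calls between libraries, and no conclusion on them is drawn from it. Repeated reads of the same molecules are argued against by C calls on lambda, which were 1.03 times as dispersed in the haploid male library as in the mean of the others. C-to-T variants at CG sites and a small number of haploid genomes in the pool, independent or shared by related males, stay open. Differences in the haploid male pairs carried over to sites 301 to 1000 bp away, with a covariance 0.00470 higher than in the other pairs (0.00338 to 0.00600). Variants linked on the same haplotype could also give this. If each genome had a fixed state and the same spread in all groups, at most 2 distinct genomes could reach the lower bound of the ratio of 4.93 (3.92 to 6.28). The ratios of 3.24 and 9.31 at coverage minimums of 5 and 20 had lower bounds of 3.07 and 3.85. Both also lie above the ratio of 3 that 3 genomes could give at most. That assumption was not measured, so the ratio sets no number of genomes, and the sample labels give no kinship. Ploidy is confounded with the library and was not tested, so it cannot be told apart from the particular genomes pooled, and other causes were not examined.

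The alate queen library had the highest genome-wide level over pooled calls. With sites weighted equally, its excess over workers fell from 0.144 to 0.0316 points. Both levels rose, from 0.700% to 0.844% in workers and from 0.844% to 0.875% in alate queens. A depth bias toward CG-poor, more methylated sequence could narrow the excess in this way, but it was not shown to be the whole cause. The remainder is smaller than the 0.0470 points by which the libraries differed on lambda. Incomplete conversion alone is argued against, since 0.0470 points lies below the interval of the excess (0.133 to 0.155). Higher methylation of the alate queen library is argued against only within the methylated bins, 2.78% of the bins. There alate queens minus workers gave -0.262 points (-0.458 to -0.0664). Outside these bins this value says nothing. In bins with 81 or more CGs the level was 0.484% in alate queens and 0.418% in workers, and with 20 or fewer CGs 2.19% and 2.20%. In the classes between, it was 1.28% and 1.20% with 21 to 40 CGs and 0.741% and 0.673% with 41 to 60. With 61 to 80 CGs it was 0.536% and 0.482%. Uneven depth between classes does not give an excess within a class. With 1 library per group, these values do not tell about the castes.

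Stretches of at least 50 consecutive CG sites without a call in 1 library, with a mean coverage of at least 3 in each other library, were picked out as data left unused. They lie outside every comparison that needs calls in all 4 libraries, because they fail its coverage minimum. There were 32 such stretches in the alate queen library, 19 in the haploid male library, 6 in the diploid male library and 0 in the worker library. Those of the alate queen library spanned 16516 bp and 1944 CGs, those of haploid males 38871 bp and 1492 CGs, and those of diploid males 28668 bp and 807 CGs. The longest of haploid males lay at 1466164 to 1472445 on scaffold 05431, and the longest of diploid males at 19427 to 28354 on scaffold 06770. The stretches were not set against each library's depth profile, so they do not tell missing sequence from low depth. With 81 or more CGs per kb, alate queens had the lowest mean coverage, 4.53 calls. With 21 to 40 CGs per kb, 10.9% of listed sites had no call in haploid males, compared with 0.823% in alate queens.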

How the results depend on the processing

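Of 234 values recomputed with 1 choice changed, 97 were kept and 137 moved. A count was kept within 1.5 times the reported count, and a distance within its scaffold bootstrap interval. A level was kept only within its binomial interval for counting error, which is narrower than the scaffold bootstrap interval printed with it. Some levels counted as moved, such as 0.733% in workers at a coverage minimum of 3, therefore lie within the printed interval (0.666 to 0.735). The split of the bins called between haploid and diploid males turned, from 42 higher and 59 lower in haploid males to 757 and 462 without the dispersion term, 501 and 395 with Fisher's exact test and 82 and 73 in bins of 5 kb, and that of the single sites turned from 57 and 32 to 5 and 24 at a coverage minimum of 20. The splits of haploid males against alate queens turned as well, from 14 and 26 bins to 627 and 336 without the dispersion term, 401 and 355 with Fisher's exact test, 51 and 44 in bins of 5 kb, 7 and 5 with thinning and 6 and 5 without a minimum level, and from 44 and 20 sites to 5 and 16 at a minimum of 20. Against workers they turned from 16 and 42 bins to 446 and 353 without the dispersion term and 290 and 253 with Fisher's exact test, and from 41 and 15 sites to 7 and 16 at a minimum of 20. Among pairs without haploid males, alate queens against workers went from 0 higher and 1 lower to 59 and 32 with Fisher's exact test, and diploid males against workers from 3 and 1 to 68 and 124 without the dispersion term and 54 and 63 with Fisher's exact test. Leaving the alate queen library out of the filters, and thinning for the level and the distance, were chosen after seeing the data. The cause was not tested, except that higher coverage minimums and thinning leave fewer calls or sites by construction. No paired analysis was possible because each group has 1 library. The planned gene lists and results by exon and intron were not run, since no gene annotation of this build was used here. At the depth of the male libraries and without extra variation between sites, 40% of simulated 20-point changes and 70% of 40-point changes were recovered, compared with 67% and 99% without the dispersion term. The choice of test thus limits the calls, while other depths were not simulated. The ratio of the mean distance with haploid males to that without was 3.24 (3.07 to 3.40) at a coverage minimum of 5 and 9.31 (3.85 to 37.5) at 20, compared with 4.93. In all settings run for the distance, each pair with haploid males was farther apart than each pair without them.

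The genome-wide level at a coverage minimum of 10 was 0.432% in workers, 0.538% in alate queens, 0.429% in haploid males and 0.426% in diploid males, and at a minimum of 3 it was 0.733%, 0.948%, 0.758% and 0.755% in the same order. Without sites above the 99th percentile of coverage it was 0.801%, 0.946%, 0.826% and 0.805%, with sites weighted equally 0.844%, 0.875%, 0.869% and 0.810%, with the lambda level subtracted 0.325%, 0.422%, 0.366% and 0.346%, and with thinning to equal coverage 0.763%, 0.801%, 0.784% and 0.732%. The alate queen level was above the others in each of these settings, but with sites weighted equally the interval of haploid males minus alate queens included 0 (-0.0117 to 0.000400). With equal weights and the lambda level subtracted together, the order turned, with 0.512% in haploid males, 0.469% in workers, 0.453% in alate queens and 0.452% in diploid males.

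Methylated sites at a coverage minimum of 10 numbered 1550 in workers, 1650 in alate queens, 1454 in haploid males and 1651 in diploid males, and at a minimum of 3 they numbered 67681, 63137, 70390 and 68630. A level of at least 20% with no test turned the order, with 61325 sites in alate queens, 50553 in workers, 45394 in diploid males and 44889 in haploid males.

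The number of single sites called between haploid and diploid males was 496 at a coverage minimum of 5, 29 at a minimum of 20, 18 with thinning and 8 without a minimum level. Between haploid males and alate queens it was 177 at a minimum of 5, 21 at a minimum of 20, 18 with thinning, 2 without a minimum level and 117 with a chi-square test. Between haploid males and workers it was 23 at a minimum of 20, 14 with thinning, 11 without a minimum level and 32 without sites above the 99th percentile. Between diploid males and alate queens it was 0 at minimums of 5 and 20, with thinning and without a minimum level.

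The number of bins called between haploid and diploid males was 32 at a coverage minimum of 10, 273 at a minimum of 3, 41 with thinning, 1219 without the dispersion term, 896 with Fisher's exact test on summed counts, 36 without a minimum level, 25 at a mean level of at least 20%, 155 in bins of 5 kb and 206 with filters that left out the alate queen library. Between haploid males and alate queens it was 24 at a minimum of 10, 130 at a minimum of 3, 20 without sites above the 99th percentile, 12 with thinning, 963 without the dispersion term, 756 with Fisher's exact test, 11 without a minimum level, 67 with at least 10 tested sites and 95 in bins of 5 kb. Between haploid males and workers it was 24 at a minimum of 10, 158 at a minimum of 3, 25 with thinning, 799 without the dispersion term, 543 with Fisher's exact test, 12 without a minimum level, 22 at a mean level of at least 20%, 108 with at least 10 tested sites, 98 in bins of 5 kb and 160 with filters that left out the alate queen library.

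Between alate queens and workers, 0 bins were called at a coverage minimum of 10, without a minimum level and without sites in opposite states, 2 at a minimum of 3 and in bins of 5 kb, 56 without the dispersion term and 91 with Fisher's exact test. Between diploid males and alate queens the count was 1 at a minimum of 10, with a difference of at least 10 points and with the median difference set to 0, where the bin was higher in diploid males. It was 4 at a minimum of 3, 5 in bins of 5 kb, 191 without the dispersion term and 139 with Fisher's exact test. It was 0 without sites above the 99th percentile, with thinning and without a minimum level. At a mean level of at least 20% it was also 0, where both bins of the main setting were left out by construction. Between diploid males and workers it was 2 at a minimum of 10, at a mean level of at least 20% and with a difference of at least 10 points, 192 without the dispersion term and 117 with Fisher's exact test. It was 0 without sites above the 99th percentile, with thinning, without a minimum level and without sites in opposite states.

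Bins in which 1 library differed from each other library numbered 53 for haploid males, 2 for diploid males and 1 for alate queens at a coverage minimum of 3. For haploid males they numbered 11 without sites above the 99th percentile and 9 with thinning, where the split turned from 8 higher and 13 lower to 5 and 4, and for diploid males 0 in both settings.

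The mean squared difference at a coverage minimum of 5 was 0.0570 between haploid and diploid males, 0.0446 between haploid males and workers, 0.0110 between alate queens and workers, 0.0191 between diploid males and alate queens and 0.0167 between diploid males and workers. At a minimum of 20 it was 0.0212 between haploid and diploid males, 0.0159 between haploid males and alate queens, 0.0208 between haploid males and workers, 0.00163 between alate queens and workers, 0.00151 between diploid males and alate queens and 0.00307 between diploid males and workers. At a mean level of at least 30% it was 0.0552 between haploid and diploid males, 0.0578 between haploid males and alate queens, 0.0471 between haploid males and workers and 0.00906 between alate queens and workers. Without sites above the 99th percentile it was 0.0516 between haploid and diploid males and 0.0517 between haploid males and alate queens.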

Other observations

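The tests below were chosen after the results were seen.

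In the bins called between haploid and diploid males, alate queens were nearer to diploid males in 77 of the 101 bins and nearer to haploid males in 24, and workers in 79 and 22. Bins chosen for a difference of the library that stands apart place the others nearer to diploid males, and alate queens and workers entered the filters, so these counts are no separate evidence of a state shared by the diploid libraries. The called bins lay on 75 scaffolds, with 2 pairs of adjacent bins, both in the same direction, compared with a mean of 0.501 pairs in 10000 random draws and at most 5.

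Methylation was more uniform among the reads of haploid males. At 52553 sites with a mean level of at least 10%, 60.8% of the variance in methylation lay between reads of the same site in haploid males (60.1 to 61.5), compared with 68.0% in diploid males, 70.9% in workers and 71.7% in alate queens. The difference from diploid males was -7.13 points (-7.81 to -6.43). Every call was methylated at 8.61% of these sites in haploid males, compared with 4.91% to 6.43% in the other libraries. Fewer distinct genomes in the haploid pool may give the same pattern as a more uniform state among haploid cells, and the 60.8% does not tell these apart.

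Some sites had a high level in a single library and low levels in the 3 others. They were picked by level alone, without a test, and no count expected from counting error was computed. The counts below therefore do not tell how many sites were methylated in 1 library only. The haploid male library had 725 sites at 50% or more where each other library was at 10% or less, in 637 bins, compared with 187 in diploid males, 134 in alate queens and 95 in workers. After thinning to equal coverage, which leaves fewer calls, the counts rose to 818, 291, 202 and 151. Sites at 10% or less in 1 library and 50% or more in the 3 others numbered 158 in haploid males, 85 in diploid males, 44 in alate queens and 34 in workers, and after thinning 197, 125, 80 and 48.

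Depth profiles differed between libraries. Across 59125 bins of 5 kb with at least 100 listed CGs, mean depth correlated between haploid males and workers with r = 0.908 and between haploid and diploid males with r = 0.814, but between alate queens and haploid males with r = 0.154, as correlations across bins, which are not replicates. In the class with 20 or fewer CGs per kb, 23.4% of listed sites had no call in haploid males, compared with 1.35% in alate queens.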
